A study of Drosophila melanogaster with 6 samples.

How the data were processed

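Total RNA from pooled eye discs of the third instar was labelled with biotin and hybridised to Affymetrix Drosophila Genome 2.0 arrays, 3 for armGFP and 3 for nmoP1. Larvae grew at 25 °C after an egg laying period of 6 to 12 h, per the labels' protocols. The replicates are called biological in the labels, and each was a separate pool of discs.

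The values deposited by the authors were log2 intensities, 1 per probe set and array, and RMA, affy and limma are named in the submitters' processing notes without versions or roles. The log base is not stated in the sources used here. It was taken as 2 because the highest value, 12.219, would as a natural log stand for 202600, above the limit of 65535 of a 16-bit scanner. The background step and the genome build are not given in the sources used here. RMA, where it was used, pulls arrays towards one distribution and sums probes into a probe set, so a uniform shift of all transcripts would not be seen and low signals are compressed.

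The table held 18952 probe sets. The 183 Affymetrix controls were left out of the tests, which left 18769. Of these 13647 had 1 gene symbol in the platform annotation, 402 had several and 4720 had none, and only those with 1 were named. Symbols were updated through Entrez numbers to the reference annotation of Drosophila assembly release 6, which 13544 probe sets matched. That annotation served only for names and for the order of genes along each arm. No probe set was named for nmo in the table used here, so its level was not analysed here, although it was planned as the first value.

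The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 4.38 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. For genes with several probe sets, the one with the highest mean over the 6 arrays stood for the gene, which gave 11983 genes. The 35 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated per list. Fry tested whether each list moved, on balance, one way, and its mixed form whether members changed in either direction. The share of called genes on the arm of nmo and within 200 genes on either side was compared with 100000 random gene sets. Tables, position tests and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

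The design, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named nmo, miple1, miple2 and Alk. It then took the 12 largest rises and 12 largest falls among genes past the threshold whose nmoP1 arrays all lay beyond the armGFP arrays. For each list it took up to 4 members past the threshold, or else up to 2 with the smallest p. Genes outside the rule were chosen after their values were seen. These are jeb, PPO1, Col4a1, NimC1, crq, lola, mam, fzy, Sgs3, Sgs4, Sgs5, Sgs7, Sgs8, Eip63E, repo and those of the gene families in the last part.

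Both steps were tested on simulated data. With 5 simulated sets of 18769 probe sets, planted log2 changes of 0.5, 1, 2 and 4 were called in 61.6%, 96.8%, 99.6% and 100% of cases, and 43 of 92845 unchanged ones were called. A cell cycle list lowered by 0.4 was called in 5 of 5 runs, with 0 other lists. The simulated genes varied independently, whereas the measured cell cycle genes had an estimated correlation of 0.44. These runs therefore cannot show how often lists whose members vary together are called in error. The planted shift was also larger than the median of -0.10 measured for that list. The position test, on 11889 genes, passed 0.05 in 5 of 5 runs with calls planted between the tip of 3L and nmo and in 0 of 5 with random calls.

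Alternatives were the replicate number as a block, centring on array medians, quantile normalization again, a filter at the median level, trended and robust variances, array weights, and leaving out probe sets whose names end in _s_at or _x_at. Leaving out each replicate, stricter thresholds, no variance moderation, 1 probe set per gene, fry and the most variable probe set per gene were also tried. Leaving out genes of 3L from its tip to nmo, and all genes of 2R and 3L, were added after seeing the data.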

Results

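Gene expression was measured in eye imaginal discs, the larval tissue that forms the adult eye, of Drosophila larvae in the third instar. The 6 samples formed 2 groups of 3. The control carried armGFP, which the submitters used as wild type, and the mutant carried armGFP with the nmoP1 allele of nmo. The gene nmo (nemo) encodes a kinase of the Nemo-like family that acts in tissue polarity and ommatidial rotation. Each sample pooled about 500 discs and was hybridised to 1 array. Median log2 values per array lay between 1.88 and 1.94, and correlations between arrays of one group lay between 0.995 and 0.998. The number of arrays limits the precision of every value below.

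The comparison of nmoP1 with armGFP asked which transcripts depend on nmo. The growth factor gene miple1, of the midkine and pleiotrophin family, rose from 1.82 ± 0.02 to 6.11 ± 0.20 (log2, SD, n = 3 each). That is a measured rise of 19.5-fold (95% CI of the log2 difference 4.06 to 4.52, limma adjusted p = 2.35e-07). The receptor gene mthl8 rose by a measured 4.27 on the log2 scale, CG11357 by 4.08 and Dnaaf3, a factor for assembly of axonemal dynein, by 3.43. The armGFP means of miple1 and of these 3 (1.16, 1.35 and 1.66) lay under every array's median, where signal may be no more than background. Their differences may therefore be measured as too small and have no order among them, and the intervals cover only the spread between arrays. Below, "at least" marks this limit alone and stands before a measured difference that also varies between arrays. On the other side PGRP-LE, an intracellular sensor of bacterial peptidoglycan, fell by 3.07 and CG32373 fell by at least 3.05, to 1.91, near the array medians. The mutated gene itself was not analysed here, because no probe set carries its name in the probe table used, so the genotype labels were not checked through it.

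In all, 128 probe sets rose and 108 fell among 18769 tested (limma, adjusted p under 0.05). Counting 1 probe set per named gene, with p adjusted over all 18769 probe sets, 166 genes were called, 83 in each direction. In all 166 the 3 nmoP1 arrays lay beyond the 3 armGFP arrays. Such separation held for 15.9% of all probe sets, against 10% by chance. Other large rises were seen for Jabba, a lipid droplet protein (2.72), and sfl, an enzyme of heparan sulfate sulfation (2.69). Vajk2 (2.15), CG15449 (2.11), CG11594 (at least 2.01) and CG9021 (1.79) also rose, as did shi, the fly dynamin (1.74), and Mgstl, a microsomal glutathione transferase (1.72). Among the genes that fell were CG12643 (-1.81), Spn, the scaffold protein spinophilin (-1.77), CG15021 (-1.36) and PPO2, a prophenoloxidase of crystal cells (-1.28). The neuropeptide precursor gene Nplp2 (-1.26), CG15784 (-1.23) and phtm, an enzyme of ecdysteroid synthesis (-1.20), fell as well. So did mthl2 (-1.14 or further), Dci, an isomerase of fatty acid oxidation (-1.14), and krimp, a piRNA pathway gene (-1.11). The largest fall of any probe set, by 4.43, was of one that has no gene name in the table used.

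Probe sets of one gene did not always move together. A second probe set for shi changed by -0.01 and another rose by 0.60, and both others for Spn changed by under 0.1 (-0.10 and -0.04). The number of calls fell when any single array was left out, with fewer samples in each such run. It was 78 higher and 47 lower without armGFP replicate 1, and 81 and 76 without armGFP replicate 2. It was 91 and 67 without armGFP replicate 3, 86 and 64 without nmoP1 replicate 1, and 68 and 35 without nmoP1 replicate 2. Without nmoP1 replicate 3 it stayed nearer to the full count, at 122 and 82. Among the genes above, the calls of CG9021, CG15021, PPO2, Nplp2 and phtm were lost when some single arrays were left out.

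**Figure D1:**
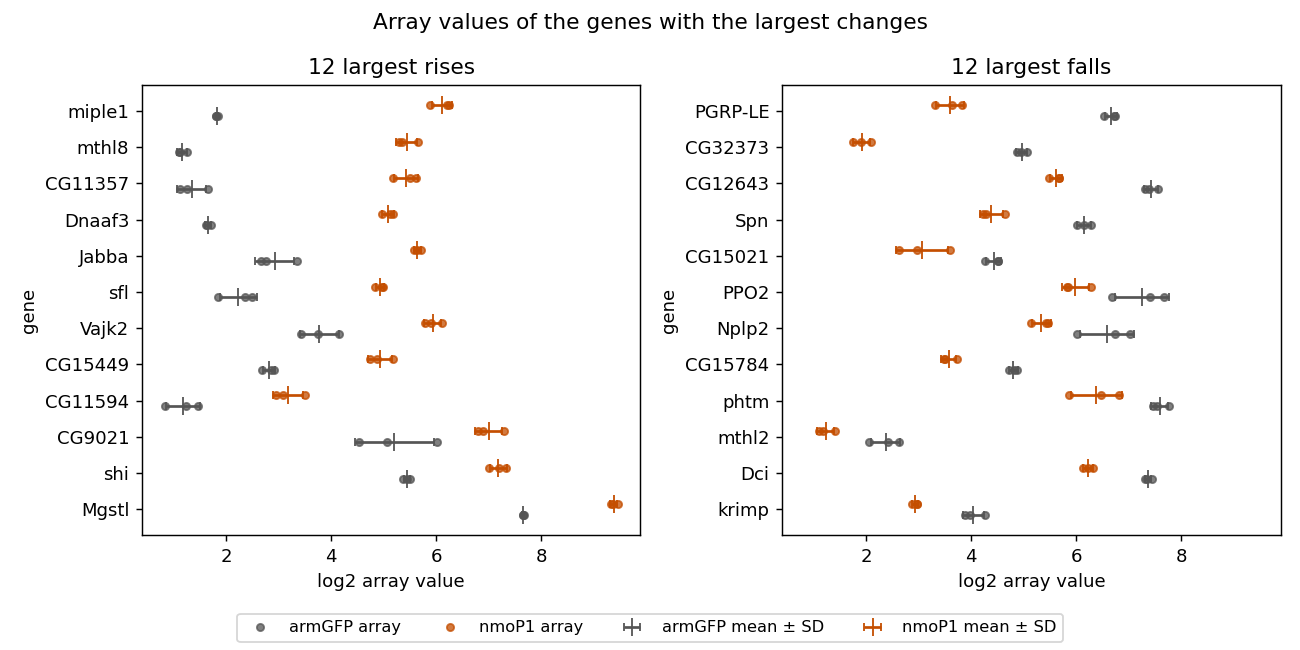
Array values (log2) of the 12 genes with the largest rises and the 12 with the largest falls in nmoP1. Points are single arrays, and vertical ticks with bars are means ± SD of 3 arrays. Only genes whose groups do not overlap were eligible, as for miple1 (1.82 against 6.11).

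The related gene miple2 did not pass the test (-0.09, adjusted p = 0.741, 9.68 ± 0.06 in armGFP against 9.59 ± 0.07 in nmoP1, n = 3 each). Alk, a receptor tyrosine kinase, lay under every array's median in both groups (1.19 and 1.04, adjusted p = 0.79), where a difference may go unseen. Its ligand gene jeb did so in armGFP, and its difference of at least 1.15 did not pass (adjusted p = 0.162). Of the genes named below, BobA, upd2, aly, bam, LysX, Ets21C and MtnC lay under these medians in both groups. Vmat and vg did so in armGFP and MtnD in nmoP1, so the differences of all these genes are limited in the same way. Of the 4 measured genes in the list of miple genes, Alk and jeb, 1 rose, and 2 rose when adjusted over the list alone. Camera called the list higher (median 0.53, adjusted p = 0.0286), a call lost with an estimated correlation (adjusted p = 0.895). Yet 2 of its genes lay higher and 2 lower, and miple1 had the largest change. Without the 3L genes from the tip to nmo, miple1 and miple2 among them, too few members were left to test. The list was written with knowledge of the study, so it is not independent evidence of its direction.

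Called genes were unevenly placed along the chromosomes. Of 165 called genes with a position, 57 lay on 3L, the arm of nmo, where 32.5 were expected (permutation p = 1e-05 over 100000 random gene sets, two-sided, the smallest p they can give). Within 200 genes of nmo on either side lay 10 called genes, against 4.08 expected (permutation p = 0.00751). On 3L, 50 of the 57 lay between the tip of the arm and nmo, including miple1, mthl8, CG11357, sfl, CG11594, CG32373 and Spn. Dci, CG15021 and mthl2 lay there too, as did Cht7, Mdr65 and msl-3, which are named below. There 6.25% of 800 tested genes were called (95% Wilson interval 4.77 to 8.15), against 1.04% elsewhere. Beyond nmo on the same arm 7 of 1544 genes were called. Arm 2R held 55 called genes against 33.7 expected (permutation p = 5e-05), with Dnaaf3, Jabba, PPO2 and krimp among them, and 3R held 13 against 41.3 (permutation p = 1e-05). The stretch from the tip to nmo was singled out after its values were seen, and without its genes 96 probe sets rose and 57 fell. Random gene sets treat neighbouring genes as independent. When the calls were instead shifted together along the gene order, 3L held as many calls in 19.5% of the shifts, 2R held as many in 21.1% and 3R as few in 16.5%. The arms were laid end to end, with 2R next to the tip of 3L, so a shift could bring calls of both together. The shares for 3L and 2R therefore cannot decide whether either arm held more calls than chance would give. Apart from the stretch, no run of as many tested genes held more than 31 calls, against 50 in it.

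**Figure D2:**
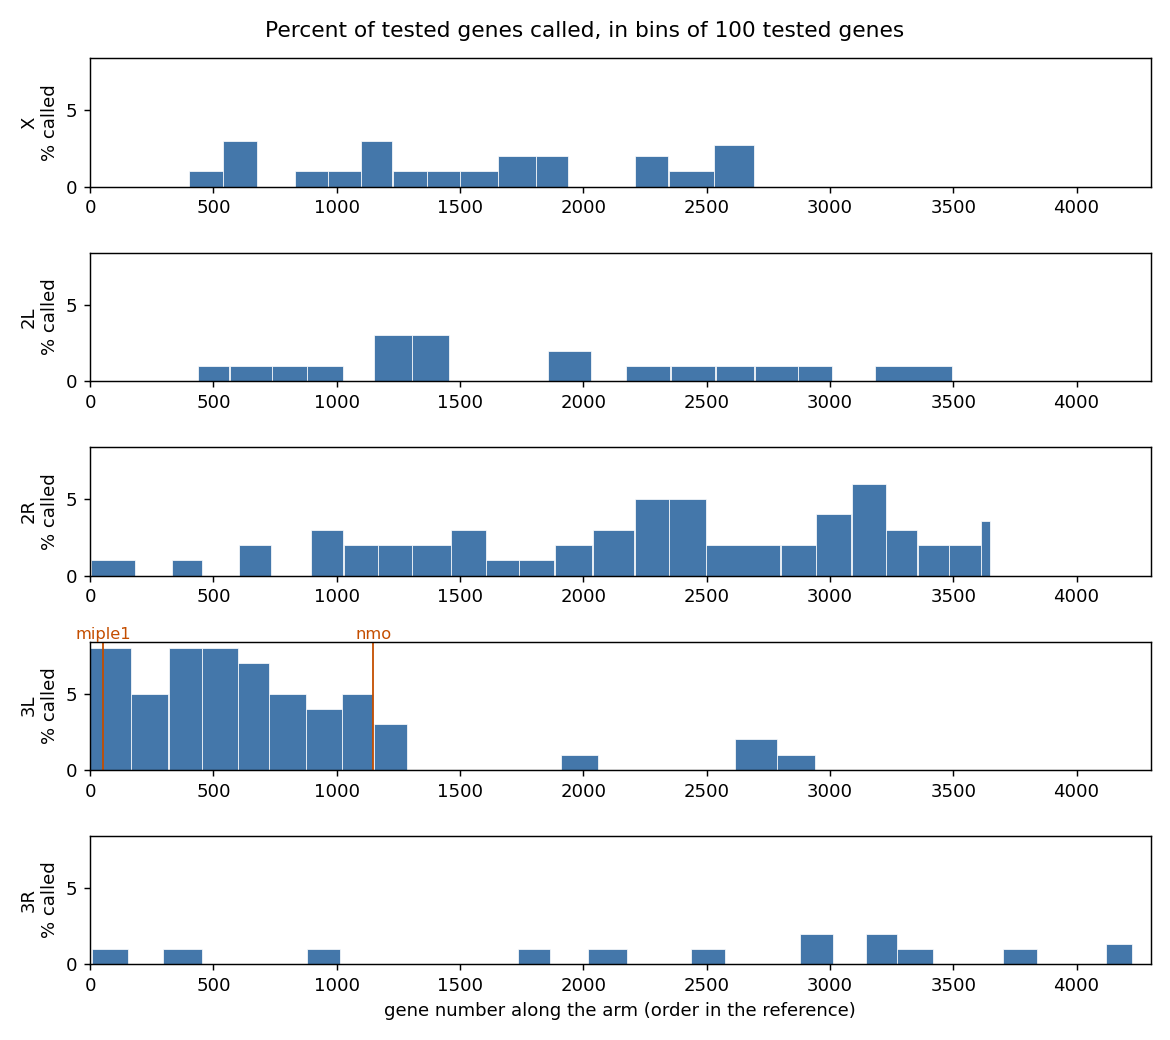
Percent of tested genes called (vertical axis) along the arms X, 2L, 2R, 3L and 3R (horizontal axis, gene number along the arm), in bins of 100 tested genes, with miple1 and nmo marked on 3L. From the tip of 3L to nmo 6.25% of genes were called, against 1.04% elsewhere.

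Genes of blood cells were lower in nmoP1 as a list (median -0.45, camera adjusted p = 1.31e-06), a call that was lost with an estimated correlation (adjusted p = 0.921) and with fry (adjusted p = 0.271). Of 20 measured hemocyte genes 2 fell, none rose and 18 did not pass, while 13 fell when adjusted over the list alone. The 2 were Glt, which encodes glutactin (-0.86, adjusted p = 0.0152), and PPO2 (-1.28, adjusted p = 0.0456). PPO1 changed by -0.99 (adjusted p = 0.0586) and Col4a1, a chain of collagen IV, by -0.67, whereas NimC1 changed by 0.17 and crq by 0.01. Either call of a single gene was lost without nmoP1 replicate 1 or other single arrays, while the list's median without that replicate was -0.44.

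Salivary gland genes were higher as a list in nmoP1 (median 0.38, mean 0.91, camera adjusted p = 0.000108; adjusted p = 0.921 with an estimated correlation). None of the 17 measured genes passed the test, nor did any when adjusted over the list alone, with 2 at an unadjusted p under 0.05 (limma). The glue protein genes Sgs3 (9.73), Sgs5 (10.42) and Sgs7 (10.56) were highest on nmoP1 replicate 1, and lay at 4.77 to 5.69 on the other nmoP1 arrays. On armGFP replicate 1 Sgs3 (5.61), Sgs5 (6.33) and Sgs7 (6.91) were also higher than on the other armGFP arrays, where they lay at 3.02 to 4.89. Without nmoP1 replicate 1 the list's median was 0.15 and its adjusted p was 0.0507. With probe sets above the median level only, which leaves out weak members, the list's median was 1.64 (camera adjusted p = 0.00198). The first principal component, with 42.0% of the variance, separated the groups. On the second, with 22.4%, nmoP1 replicate 1 lay at 15.9 and the other nmoP1 arrays at -12.4 and -13.7. That array's 5′ minus 3′ difference, a measure of RNA quality, was the lowest of the 6 for 3 controls. It was -0.67 for actin, against -0.39 to -0.16 on the others, -1.19 for eIF-4a, against -0.98 to -0.66, and -3.46 for Act5C, against -3.27 to -2.47. For GAPDH it was -0.50, against -0.59 to -0.52.

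**Figure D3:**
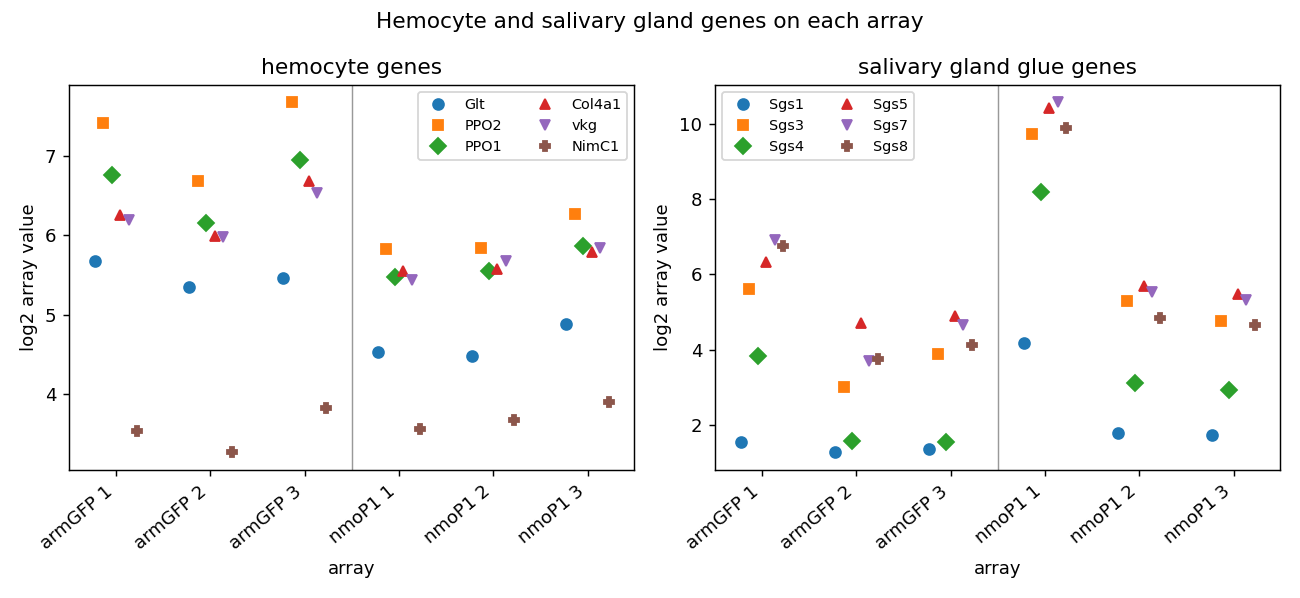
Log2 array values (vertical axis) of 6 hemocyte genes and 6 salivary gland glue genes on each of the 6 arrays (horizontal axis). Each point is 1 gene on 1 array; glue genes are highest on nmoP1 replicate 1, as Sgs7 at 10.56, and PPO2 is lower on all 3 nmoP1 arrays.

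Cell cycle genes were lower as a list (median -0.10, camera adjusted p = 0.0286; adjusted p = 0.921 with an estimated correlation), with 0 of 25 past the test, 0 when adjusted over the list alone and 2 at an unadjusted p under 0.05 (limma). Another probe set of fzy rose (0.83, adjusted p = 0.0399), while the one that stood for it was at -0.07. The closest to the threshold were RnrL, the large subunit of ribonucleotide reductase (-0.27), and tum (-0.25). Heat shock genes were higher as a list (median 0.15, camera adjusted p = 0.0286; adjusted p = 0.921 with an estimated correlation), with 0 of 8 past the test, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05 (limma). Hsp68 changed by 0.54 and stv by 0.35. Without armGFP replicate 3 the cell cycle median was -0.06 (adjusted p = 0.531) and the heat shock median 0.06 (adjusted p = 0.375). Without nmoP1 replicate 1 they were -0.12 (adjusted p = 0.074) and 0.10 (adjusted p = 0.232), and without nmoP1 replicate 2 the cell cycle median was -0.07 (adjusted p = 0.16). The calls were kept without any other single array. Without armGFP replicate 1 the medians were -0.15 and 0.20 (camera adjusted p = 0.000979 and 0.0115). With array weights both calls were lost (adjusted p = 0.0773 and 0.203). The cell cycle call was also lost with quantile normalization again (adjusted p = 0.099), with probe sets above the median level only (0.146) and with the most variable probe set per gene (0.123). The heat shock call was also lost without probe sets ending in _s_at or _x_at (adjusted p = 0.23) and without the 3L genes from the tip to nmo (0.0508), and fry called neither list. These 5 lists of 35 were the ones called, and 0 were called with an estimated correlation, where 1 had an unadjusted p under 0.05.

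Genes that pattern the eye did not pass the test by the probe set that stood for each. In 13 lists of eye development and signalling, 0 of 159 measured genes were called by limma in this way, against 166 of all 11983. An unadjusted p under 0.05 (limma) was found for 19 of the 159, against 1981 of all 18769 probe sets. The first counts genes and the second all probe sets, unnamed ones included, so the comparison cannot show an excess. Fry's mixed test gave unadjusted p = 1.04e-06 for photoreceptor, 9.05e-05 for cone and pigment cell and 0.000386 for retinal determination genes. It gave 0.00106 for the furrow and proneural, 0.00425 for EGFR and 0.0441 for Wingless lists, and above 0.05 for the others. Outside eye development the same mixed test gave unadjusted p = 6.9e-07 for ribosomal proteins and 8.79e-05 for detoxification, but 0.736 for fat body genes. Small values of this test were therefore not particular to genes that pattern the eye. Changes in both directions stay open for the eye lists. Other probe sets rose for lola (0.77, adjusted p = 0.0131), whose main one was at -0.11, and for mam (0.43, adjusted p = 0.0368), whose main one was at 0.08. The largest of the shifts in these lists' medians was -0.11, for the morphogenetic furrow and proneural genes (n = 13, adjusted p = 0.3), where phyl changed by -0.22 and gl by -0.22. Retinal determination genes had a median of -0.01 (adjusted p = 0.569), with toy at 0.27 and Optix at 0.21, and toy rose when adjusted over the list alone. Photoreceptor genes had a median of -0.09 (adjusted p = 0.26), with the receptor gene sev at 0.35 and the transcription factor gene lz at -0.36; adjusted over the list alone, 1 rose and 1 fell. Cone and pigment cell genes had a median of -0.04 (adjusted p = 0.879), with hbs at 0.28, and here too 1 rose and 1 fell when adjusted over the list alone.

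Planar cell polarity genes had a median of -0.01 (adjusted p = 0.879), with fj at -0.18 and frtz at -0.13. Genes of ommatidial rotation, adhesion and cytoskeleton had a median of 0.00 (adjusted p = 0.784), with lama at 0.35 and ed at 0.23. EGFR signalling genes had a median of -0.07 (adjusted p = 0.569), with ksr at -0.18 and the inhibitor gene aos at -0.31, which fell when adjusted over the list alone. For Wingless signalling the median was 0.09 (adjusted p = 0.26), with vg at 0.30 and Dll at -0.18. For dorsal eye and Iroquois genes it was 0.04 (adjusted p = 0.3), with Doc2 at 0.11. For Notch signalling it was 0.03 (adjusted p = 0.707), with BobA at 0.27 and E(spl)mdelta-HLH at -0.28. Hedgehog and Dpp genes had a median of -0.06 (adjusted p = 0.582), with dpp at -0.12 and cos at -0.08. JAK/STAT genes had one of -0.01 (adjusted p = 0.879), with Stat92E at -0.13 and upd2 at 0.14. Hippo genes had one of -0.05 (adjusted p = 0.585), with sav at -0.13 and hpo at -0.13. In the 9 of these 13 lists whose count is not given, 0 genes passed when adjusted over the list alone.

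Single genes changed in 4 further pathway lists. Phototransduction had 1 of 13 genes up, Arr1, an arrestin of photoreceptors (at least 1.07, adjusted p = 0.0015; list median 0.04, adjusted p = 0.0539). Detoxification had 2 of 45 genes down, Cyp4p1 (-0.53) and GstE5 (-0.68), with a list median of -0.01 (adjusted p = 0.784). In the ecdysone list phtm fell and 25 of 26 genes did not pass (median 0.09, adjusted p = 0.26). Eip63E, which lies between the tip of 3L and nmo, was at -1.84 (adjusted p = 0.057). Ribosomal protein genes had 1 of 40 up, RpL22-like (0.39), with a median of 0.01 (adjusted p = 0.26). The calls of Cyp4p1, GstE5, phtm and RpL22-like were lost when some single arrays were left out, and these and that of Arr1 without variance moderation. Adjusted over the list alone, the counts were 1, 2, 2 and 1 in that order. Apoptosis and JNK genes had a median of -0.06 (adjusted p = 0.375), with Ets21C at -0.31 and Dcp-1 at -0.25. Immune effector genes had one of 0.03 (adjusted p = 0.476), with LysX at 0.18 and Drs at -0.17. Eye pigment genes had one of -0.02 (adjusted p = 0.879), with car at 0.15. None of these 3 lists had a gene past the test or when adjusted over the list alone.

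Among markers of other tissues, glia had 1 of 13 genes down, Mdr65, a transporter of the blood-brain barrier (-0.81, adjusted p = 0.017). That call was lost without nmoP1 replicate 2 or 3, and Mdr65 lies between the tip of 3L and nmo. Adjusted over the list alone, 3 were down. The list median was -0.04 (adjusted p = 0.26) and repo was at -0.29. Fat body genes had a median of 0.04 (adjusted p = 0.375), with Fbp1 at 0.90 and Fbp2 at 0.37. Muscle genes had one of -0.10 (adjusted p = 0.582), with sls at 0.39 and Zasp52 at -0.10. The median was 0.02 for the antennal disc (adjusted p = 0.879), with bab1 at 0.32, and -0.04 for larval brain neurons (adjusted p = 0.784), with Nplp1 at 0.44 and Vmat at 0.39. It was 0.00 for the trachea (adjusted p = 0.879), with uif at -0.37 and bnl at 0.19, and 0.02 for the midgut (adjusted p = 0.569), with LManII at 0.31. It was -0.03 for the testis and male germline (adjusted p = 0.707), with aly at 0.20 and bam at -0.24. Peripodial and disc margin genes had a median of -0.01 (adjusted p = 0.935), with puc at -0.25 and bowl at -0.16. Genes of sex and dosage compensation had one of 0.00 (adjusted p = 0.879), with tra at 0.11 and msl-2 at -0.10. Apart from the glial list, none of the lists in this paragraph had a gene past the test or when adjusted over the list alone. Over all 35 lists, median, mean and test differed in sign for 9, none of them called.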

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

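The test of the control probe sets was not among those fixed before the data were examined. The array's own control probe sets were not used in the comparisons above. Of 183 of them, 1 of 4 that share an ID differed between the groups (limma adjusted p = 0.0474 over all probe sets). Over the controls alone its limma adjusted p was 0.105. It was at 1.05 ± 0.04 in armGFP and 2.27 ± 0.55 in nmoP1 (n = 3 each), a measured log2 change of 1.22. Its armGFP mean lay under every array's median, which limits that value. The smallest unadjusted p of the other 3 was 0.245 (limma). From general knowledge of that ID the 4 were taken to represent the bacterial lac operon, which was not checked here, and whether the nmoP1 allele carries lacZ was not examined.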

How the results depend on the processing

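The settings that leave out genes of 3L or 2R were chosen after seeing the data; the others were fixed before. The main counts were 128 higher, 108 lower and 5 lists. With array weights 186 probe sets were lower and 3 lists called. Without variance moderation the counts were 15 higher and 6 lower. With p adjusted over 1 probe set per named gene 79 were higher, where counting such probe sets alone, before that adjustment, gave 83. At a log2 change of 1 or more they were 44 and 26, and at adjusted p under 0.01 they were 64 and 32, by construction. Without 3L genes from the tip to nmo 57 were lower and 3 lists called, and without 2R and 3L genes 56 were higher and 34 lower, with fewer genes tested. Lists called were 3 for probe sets above the median level, 0 with an estimated correlation and 1 with fry. For array weights, the level filter and variance moderation the cause was not tested. Leaving out single replicates gave 68 to 122 higher, 35 to 82 lower and 2 to 7 lists, with fewer samples. The share of called genes on 3L was 34.5%, and 34.9% to 39.2% without single replicates; within 200 genes of nmo it was 6.06%, and 6.98% to 10.8%. Against random gene sets both stayed past their threshold in every alternative run. Shifting the calls along the gene order gave as many on 3L in 19.5% of shifts. As a shift could bring calls of 2R and 3L together, that share cannot decide. With the replicate number as a block 108 were higher and 94 lower, 170 of them among the main 236. Same-numbered arrays deviated together with correlations of 0.0989, 0.0534 and -0.0349, so the numbers were not taken to pair samples. Of 615 alternative values for 39 called features named in the text or in the lists, further probe sets of a gene left out, 493 stayed past the threshold, 122 did not and 0 changed direction. The groups did not overlap in any called gene, so leaving out an array could not reverse its direction. For 10 features, miple1 among them, every alternative run passed. Weak signal limits what can be seen, since array medians lay at 1.88 to 1.94.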

Other observations

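The gene families in this paragraph were chosen after their values were seen, and so were all tests in this part, except that the test of the arm of nmo and the splits of the arrays had been set out before the data were examined. Of 4 measured metallothionein genes, which bind metal ions, MtnA (-0.97, adjusted p = 0.00312) and MtnB (-1.08, adjusted p = 0.047) fell. MtnD (-0.26) and MtnC (-0.04) did not pass the test. MtnC lay under every array's median in both groups and MtnD did so in nmoP1. These values therefore cannot show whether the whole family fell. Of 4 Vajk genes, Vajk2 (2.15) and Vajk4 (0.73) rose. Of 14 methuselah-like receptor genes, mthl8 rose, and mthl2 and mthl4 (-0.58) fell, while a second probe set of mthl4 changed by -0.01 (adjusted p = 0.988). Of 9 genes of ecdysteroid synthesis only phtm passed the test. The genes nvd (-1.31), sad (-0.72), spok (-0.61), sro (-0.49) and dib (-0.36) lay lower too, each at an unadjusted p under 0.05 (limma). The rest lay under or near the array medians, where a difference may go unseen. On nmoP1 replicate 3, spok (7.50) and nvd (4.22) lay within the armGFP range (7.24 to 7.59 and 4.17 to 4.66). There sad, sro and dib lay below every armGFP array. Whether tissue other than the disc contributes to these values was not tested. Of 5 genes of the dosage compensation proteins msl-3 fell (-0.87), and its second probe set fell by 1.38. Of 10 chitinase genes Cht7 rose (0.68) and Cht6 fell (-0.42), while another probe set of Cht6 rose by 1.58. The calls of MtnB, Vajk4, mthl4, Cht6 and Cht7 were lost when some single arrays were left out.

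Called genes were concentrated between the tip of 3L and nmo. For the whole of 3L, random gene sets gave permutation p = 1e-05, the smallest they can give. They treat neighbouring genes as independent, and the stretch was picked from these same calls. This test therefore cannot exclude that calls of neighbouring genes fell there by chance. Linked differences between the armGFP and nmoP1 strains are a candidate explanation. Among genes of the stretch that were not called, 18.4% had an unadjusted p under 0.05 (limma) against 9.82% elsewhere, a ratio of 1.87 (95% CI 1.59 to 2.20). The interval treats neighbouring genes as independent. As the stretch was picked for its calls, the ratio cannot tell linked differences from other causes of changes there. Sequence variants under the probes may also contribute. Of 6 other probe sets of called genes there only 4 (66.7%) followed, and those that did not were all of Spn. These are too few to decide. Shifting the calls along the gene order gave as many in the stretch in 0.681% of shifts but as many on all of 3L in 19.5%. The share for all of 3L cannot decide, as a shift could bring calls of 2R and 3L together. Apart from the stretch, no run of as many tested genes held more than 31 calls, against 50 in it. As miple1 lies in the stretch, its regulation by nmo and a linked difference both stay open. The same holds for the other called genes there, Mdr65, msl-3 and Cht7 among them.

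Hemocyte genes were lower in nmoP1 at the preset correlation, but the list's call was lost with an estimated one (adjusted p = 0.921). An effect of nmoP1 replicate 1 alone is argued against, as the list's median without it was -0.44. Fewer blood cells in the mutant pools may explain it, as the list's genes varied together within groups (mean correlation 0.363, against a median of 0.0182 in random lists of like level, and a share of 0.0002 of 10000 such lists reached it). As members that vary together weaken the list's test, a difference in blood cells between pools that is unrelated to genotype stays open. NimC1 (0.17) and crq (0.01) did not follow, lz is also expressed in the eye disc, and an effect of nmo on these genes was not tested.

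Salivary gland genes were high on nmoP1 replicate 1. All 6 Sgs genes were highest there, with a median excess of 4.98 on the log2 scale over the other nmoP1 arrays. Salivary gland tissue in that pool is a candidate source, but these values restate the pattern and cannot test it. On armGFP replicate 1 Sgs3 (5.61), Sgs4 (3.83), Sgs7 (6.91) and Sgs8 (6.75) were higher than on the other armGFP arrays too, so the excess is not found in nmoP1 alone, while fat body genes had a median excess of 0.46 on nmoP1 replicate 1 but Fbp1 was highest on nmoP1 replicate 2 (4.82 against 4.40), which leaves open whether other tissue came with it. Whether those discs were also of a later stage stays open. The ecdysone list had a median excess of 0.11 on that array, with 20 of 26 genes higher, and its members went both ways. Apart from that stage, no biological explanation was tested.

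The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 236 called probe sets, 1 of the 10 splits reached that number, and the highest of the others gave 1. For gene lists the real split gave 5, the highest of the others gave 9, and 6 of the 10 splits gave as many as the real one.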
